A study of Mus musculus with 6 samples.

How the data were processed

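Polyadenylated RNA of mouse E14 embryonic stem cells was sequenced 3 days after transfection with a control siRNA or an siRNA against Npm1. There were 3 samples in each group, 6 in all. Per the labels' protocols, total RNA was purified with TRIzol, checked for integrity, and made into stranded, poly(A)-selected libraries that were sequenced from a single end. Per the submitters' processing notes, the tools were FastQC, Trimmomatic 0.36, STAR and DESeq2, on the mouse build GRCm38 (mm10). How reads were counted over genes, whether strand was used, the gene annotation and the settings of the model are not given in the sources used here. Sample groups were taken from the sample titles.

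The data analysed were the authors' deposited table of their own comparison, with 1 row per gene and no values per library. Its mean column is a signal value that the authors made by dividing read counts by a scaling factor per library and averaging over all 6 libraries, per the file headers, which are those of DESeq2. It is called the mean normalized count here. Its log2 fold change column holds the authors' deposited log2 ratio of the groups. The header does not state the direction of that ratio. Npm1 has a negative value, so the ratio was read as Npm1 siRNA over control siRNA, and every direction given here rests on that reading. The p-value column holds the authors' unadjusted p per gene, as deposited, and no adjusted p was given in the table. Of 52535 rows, 27423 had a mean of 0 and no test. The names of 26 rows had been turned into calendar dates, as spreadsheet programs do to some gene symbols. Of those, 17 were tested, 0 passed the threshold, and none was matched to a gene.

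The design fixed before the data were examined was a count model, or limma on log2 values, fitted to the 6 libraries. Neither could be fitted without values per library. In its place, the authors' p-values were adjusted by the Benjamini-Hochberg method over the 14284 genes with a mean normalized count of at least 10. A gene was called higher or lower at an adjusted p under 0.05, with no threshold on the fold change in the main result. A standard error was computed for each gene as the log2 fold change divided by the normal quantile of its two-sided p, which is exact for a Wald test and approximate otherwise. The 95% intervals printed are the log2 fold change plus and minus the normal quantile times that standard error. No SD or value per sample can be given.

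The total depth per library is unknown. Genes seen by a single read in a single library have a mean that gives that library's relative scaling factor. All 1314 genes with a mean under 0.19 lay on 1 of 6 such steps within a tolerance of 1e-06, 3 with a positive and 3 with a negative fold change. These gave scaling factors between 0.923 and 1.06. The mean normalized counts summed to 27631017, of which 7.78% came from mitochondrial genes and 10.8% from the 10 most abundant genes. The median standard error was 0.15 on the log2 scale over the tested genes, 0.08 for genes with a mean of at least 1000, and 0.65 for genes with a mean between 10 and 50.

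Of the tested genes, 13906 (97.4%) were matched by a unique symbol to the GENCODE annotation of GRCm38, which gave coordinates, biotype, and the length and GC content of the longest transcript. Before the data were examined, 24 gene lists were fixed. They cover ribosome biogenesis, RNA polymerase I, ribosomal proteins, p53 targets, naive and formative pluripotency, primitive endoderm, mesoderm, neuroectoderm, trophectoderm, the 2-cell-like state, germline genes, repressive chromatin, the interferon response, the integrated and unfolded protein stress responses, the cell cycle, Myc-dependent growth, glycolysis and hypoxia, sterol synthesis, fibroblasts, replication histones, mitochondrially encoded genes, olfactory and vomeronasal receptors, and clustered protocadherins. Lists with at least 5 measured members, 23 in all, were tested with limma's camera on the signed normal quantile of each gene's p, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 23 lists. A correlation estimated from the libraries, and a test such as fry, need values per library and could not be run, so no list's call was checked with an estimated correlation. Each list's median was also placed among 10000 random lists of the same size matched on mean expression. The random lists drew each gene independently, so these percentiles take no account of correlation between the genes of a list. Shares of genes per chromosome were compared with Fisher's exact test, two-sided.

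Genes named by rule were Npm1, the 10 with the highest and the 10 with the lowest log2 fold change among called genes with a mean of at least 50, and up to 3 called members per list, or 2 by abundance where none was called. Predicted genes, symbols ending in Rik and pseudogenes were passed over, which left out 1 gene from the highest and none from the lowest. The part of the rule that asked for no overlap between the 3 samples of each group could not be applied. Some genes that the rule takes are not reported here. Other genes named in the text were chosen after their values were seen.

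Alternatives fixed in advance were no filter on low means, a mean of at least 50, a fold of at least 2, a test against a fold of 1.2, and protein-coding genes only. Recentring of the fold changes, subtraction of a fitted trend on transcript length and GC content, the mean threshold giving the most calls, ranks in place of normal quantiles, and preset correlations of 0 and 0.05 were added after seeing the data. The procedure was tested on simulated data for this comparison, with 14284 genes of the observed means and errors and 50 changed genes per fold size. It called 20% of genes changed 1.2-fold, 42% at 1.5-fold, 72% at 2-fold and 74% at 4-fold. Among changed genes with a mean of at least 500, it called 39.1% at 1.2-fold and 100% from 1.5-fold on. Of all calls, 2.80% were unchanged genes. The simulated genes were independent, and each p was computed from the same error that generated the change. The share of unchanged genes was therefore held low by design and is no check of the authors' p-values. The simulation gave 107 calls against 614 in the data, so its threshold on the unadjusted p was stricter and its shares called may be too low. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, patsy 1.0.2 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.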

Results

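RNA sequencing measured polyadenylated transcripts in E14 cells, a line of mouse embryonic stem cells kept here in serum-free medium with leukaemia inhibitory factor and kinase inhibitors that hold them in naive pluripotency. Cells received a control siRNA or an siRNA against Npm1 and were collected 3 days later, with 3 samples in each group. Npm1 encodes nucleophosmin, an abundant protein of the granular component of the nucleolus, where ribosomal subunits are assembled. The series title asks whether this component is needed to hold nucleolus-associated chromatin domains at nucleoli and to set up repressive chromatin, and this comparison gives the transcript levels once Npm1 was lowered. All gene values come from the authors' deposited table, which pools the 6 libraries, so errors are standard errors implied by each fold change and p. The labels do not say whether the samples were separate cultures, so p-values measure only the spread between these samples, which may be technical.

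Npm1 fell to 45.3% of the control level in the authors' deposited table (log2 -1.14, 95% interval -1.29 to -0.996, Benjamini-Hochberg adjusted p = 5.35e-49). The direction of all ratios was itself read from Npm1, so this fall is not a separate check of the group labels. Of 14284 genes tested, 318 rose and 296 fell after Npm1 siRNA. Targets of p53 rose as a list. Germline genes fell as a list, as did the joint list of integrated and unfolded protein stress response genes. No member of the ribosome biogenesis list passed the test, and the core pluripotency factors Pou5f1, Sox2 and Nanog did not either. Most changes were small, with a median fold of 1.28 among the genes that rose and a median level of 73.7% of control among those that fell.

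Npm1 lies on chromosome 11 from 33152287 to 33163206 (GRCm38) and was the gene of rank 10 by mean normalized count, at 135425 in the authors' deposited table, or 0.490% of the sum over all genes. It remained among the abundant transcripts after the knockdown, at an approximate 84458 normalized counts against 186392 in control, both derived from the pooled mean and fold change of the authors' deposited table. The calls made up 4.30% of the tested genes, and 591 of the 614 were protein coding. A fold of at least 2 was reached by 21 of the genes that rose and 37 of those that fell, and with a test against a fold of 1.2 the counts were 9 and 12. Of the genes named by rule, Tesk1, Klk1, Taf1d, Utf1, Mael, Wiz, Ldha, Cct3 and mt-Nd2 were among those that lost their call once a trend on transcript length and GC content was subtracted. Several of these kept most of their size and ended close to the threshold, such as Klk1 (log2 -1.23 before and -1.18 after, adjusted p = 0.0649), Mael (-0.99 and -0.92, adjusted p = 0.0629) and Taf1d (0.22 and 0.21, adjusted p = 0.0766), with the value before from the authors' deposited table. Utf1 (0.48 and 0.33) and Wiz (0.32 and 0.22) moved further from the value in the authors' deposited table. With no filter on low means, Fam196a, Tesk1, Klk1, Taf1d, Zscan4e, Mael, Zfp57, Ddx58, Vldlr, Ldha, Cct3 and mt-Nd2 had adjusted p between 0.0514 and 0.0767.

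**Figure D1:**
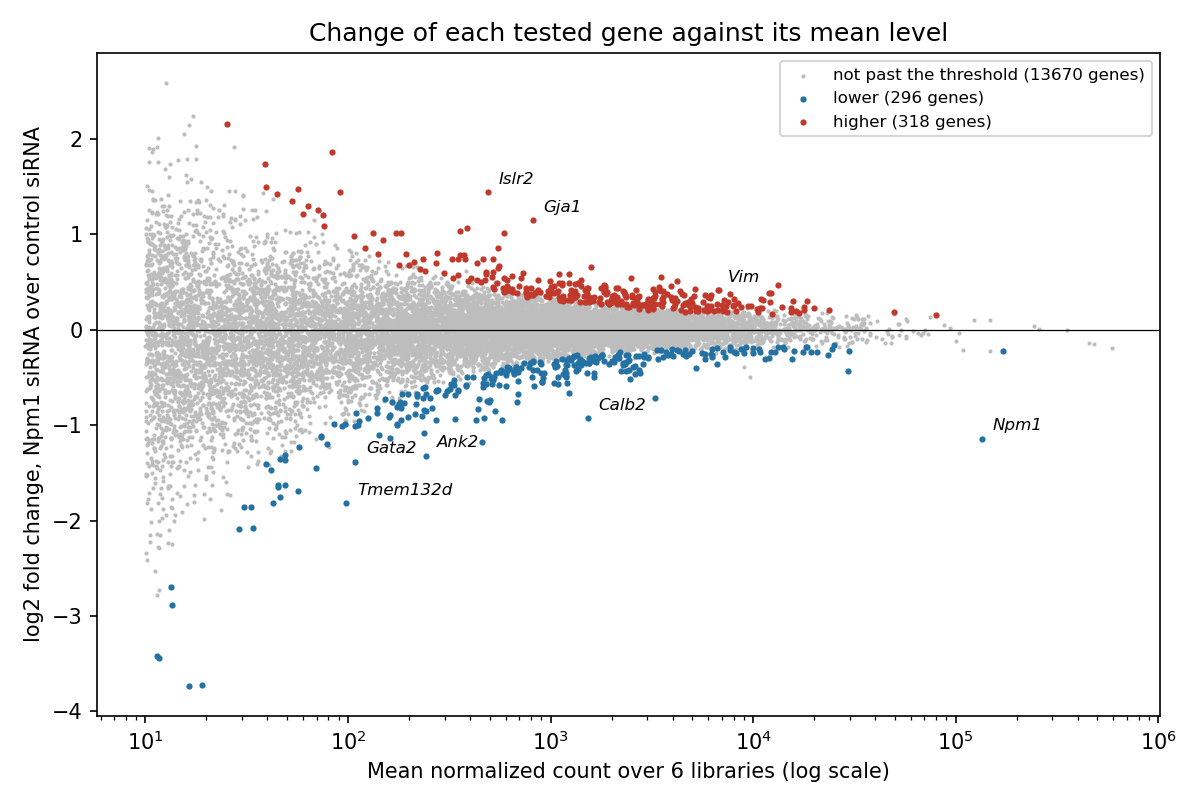
Log2 fold change of Npm1 siRNA over control siRNA (vertical axis) against the mean normalized count over 6 libraries (horizontal axis, log scale), each point being 1 of 14284 tested genes, with 318 higher genes in red, 296 lower genes in blue and the rest in grey. Npm1 stands apart among the abundant genes at a log2 fold change of -1.14 in the authors' deposited table, and low-mean genes needed far greater changes to pass.

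The genes with the greatest rise were led in precision by Islr2 and Gja1. Islr2, a membrane protein of developing neurons (chromosome 9, 58196297 to 58204319), rose 2.72-fold in the authors' deposited table (log2 1.44, 95% interval 1.16 to 1.72). Gja1, a gap junction connexin (chromosome 10, 56377330 to 56402513), rose with a log2 fold change of 1.15 (95% interval 0.89 to 1.41) in the authors' deposited table. Both were measured with implied standard errors of 0.14 and 0.13, whereas the other 8 genes of this group had means under 100 and standard errors of 0.34 to 0.43. These were the cell-surface nucleotidase Nt5e (log2 1.47), the T-box factor Tbx20 (1.44), the zinc finger factor Tshz1 (1.34), the neuronal protein Nsg2 (1.29), the neural progenitor factor Sox1 (1.26), Fam196a (1.21), the trophoblast surface protein Plet1 (1.198) and the kinase Tesk1 (1.09), by the authors' deposited table.

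The genes with the greatest fall included Ank2, Tmem132d and Gata2. Ank2, an ankyrin that ties membrane proteins to the spectrin skeleton, fell to 40.1% (log2 -1.32, 95% interval -1.75 to -0.89, the authors' deposited table), and Tmem132d, a membrane protein, to 28.4% (log2 -1.82, -2.48 to -1.15). The transcription factor Gata2 fell by 1.38 on the log2 scale in the authors' deposited table, with an implied standard error of 0.31. Others were the secreted serpin Serpinf1 (log2 -1.69), the sphingomyelin synthase Sgms2 (-1.45), the kallikrein Klk1 (-1.23), the glutathione peroxidase Gpx6 (-1.198) and AC129016.2, a gene with no standard name, (-1.13), by the authors' deposited table, alongside Npm1 itself.

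Of 23 gene lists tested, 5 passed limma's camera test. Among 35 measured p53 targets, 8 rose, none fell and 27 did not pass, and 13 rose when adjusted over the list alone. The list median was a log2 fold change of 0.20 (camera adjusted p = 6.23e-09), above all of 10000 matched random lists. Plk2, a stress-induced kinase, rose 1.43-fold in the authors' deposited table (log2 0.51, 95% interval 0.30 to 0.72). Ei24 and Psrc1 followed at log2 0.42 each, and Mdm2, the ubiquitin ligase that degrades p53, rose by 0.24 in the authors' deposited table (adjusted p = 0.0401). The other members that rose were Sesn2, Trp53inp1, Ccng1 and Gtse1, with log2 fold changes from 0.26 to 0.35 in the authors' deposited table. Cdkn1a, the cell-cycle inhibitor induced by p53, had a log2 fold change of 0.11 (adjusted p = 0.396) and Trp53 itself 0.06 (adjusted p = 0.692) in the authors' deposited table.

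Germline and meiosis genes, many of which are silenced by DNA methylation in somatic cells, fell as a list. Of 32 measured members, 8 fell, none rose and 24 did not pass, and 11 fell when adjusted over the list alone. The list median was a log2 fold change of -0.37 (camera adjusted p = 2.26e-09), below all of 10000 matched random lists. Mael and Mov10l1, both of the piRNA pathway, fell to 50.5% and 53.2% of control in the authors' deposited table (log2 -0.99 and -0.91). Smc1b, a meiotic cohesin subunit, fell by 0.76, Meioc, a meiotic regulator, by 0.53 and Tex14, needed for germ cell bridges, by 0.45 on the log2 scale in the authors' deposited table. The X-linked Rhox2a (log2 -1.81) and Xlr3a (-1.09) and the tubulin Tuba3a (-0.36) also fell in the authors' deposited table, and these have close paralogs with which reads could be shared, so their values are uncertain. Dazl, an RNA-binding protein of germ cells, had a log2 fold change of -0.18 (adjusted p = 0.376) in the authors' deposited table.

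The list of integrated and unfolded protein stress response genes also fell. Of 29 measured members, 6 fell, none rose and 23 did not pass, and 9 fell when adjusted over the list alone. The median log2 fold change was -0.13 (camera adjusted p = 3.86e-07), below all of 10000 matched random lists. The members that fell were enzymes of serine synthesis and mitochondrial folate metabolism (Phgdh, Psat1 and Mthfd2), the alanine aminotransferase Gpt2, the stress-induced chromatin protein Nupr1 and the lipoprotein receptor Vldlr. Mthfd2 fell to 74.4% of control in the authors' deposited table (log2 -0.43, 95% interval -0.56 to -0.29), Phgdh to 74.9% (log2 -0.42) and Vldlr to 62.5% (log2 -0.68). Of the members that did not pass, the chaperone Hspa5 had a log2 fold change of -0.06, Ddit3 -0.02 and Trib3 -0.07 in the authors' deposited table, and 25 of the 29 values were negative. Atf4, the transcription factor that drives much of this list, had a log2 fold change of -0.04 (adjusted p = 0.854) in the authors' deposited table.

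**Figure D2:**
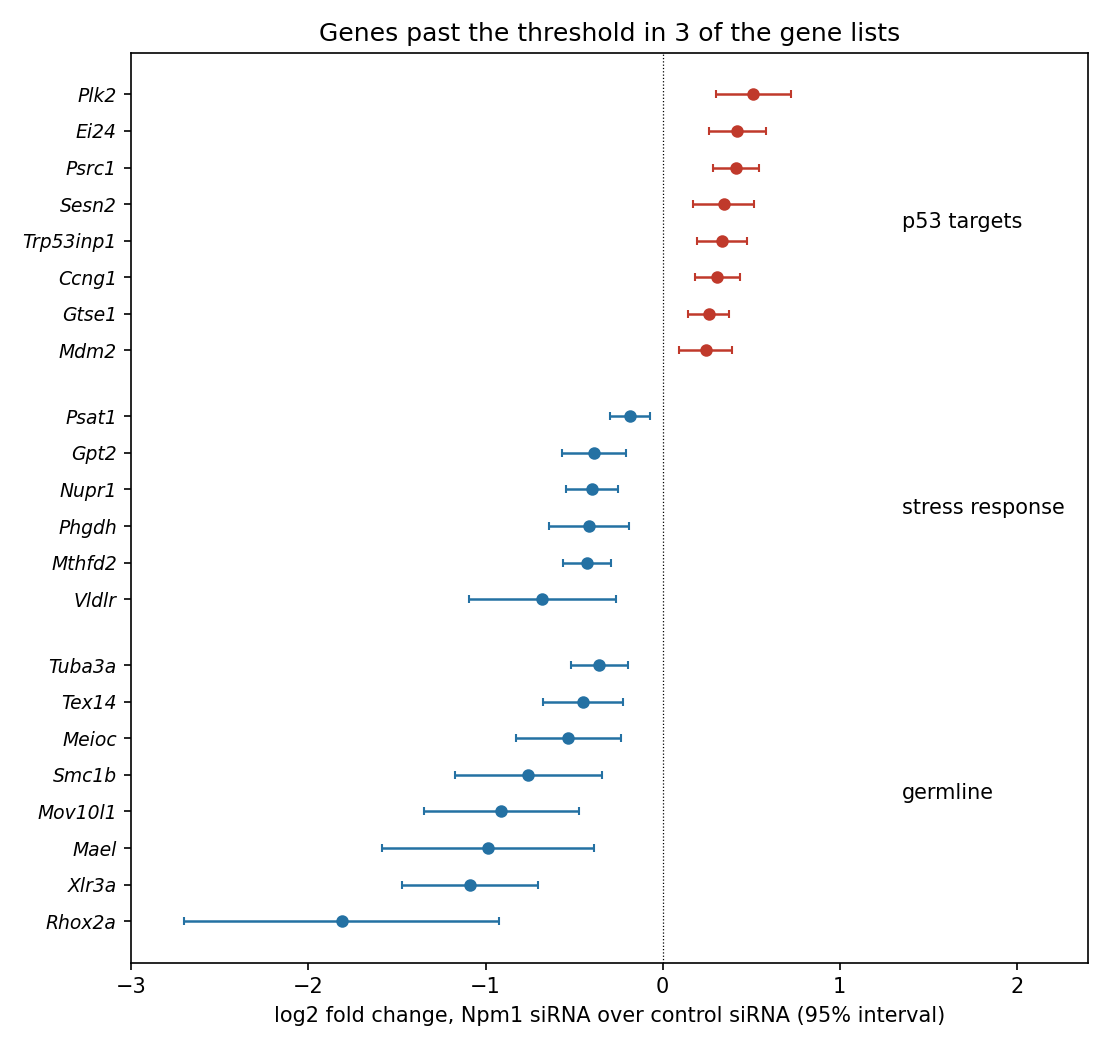
Log2 fold change of Npm1 siRNA over control siRNA (horizontal axis) for each gene past the threshold in the lists of p53 targets (8 genes, red, higher), stress response (6 genes, blue, lower) and germline genes (8 genes, blue, lower), with bars for the 95% interval implied by the p in the authors' deposited table. The p53 targets lie between 0.24 and 0.51, the stress response genes between -0.68 (Vldlr) and -0.18 (Psat1), and the germline genes spread more widely, from -1.81 to -0.36.

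Genes of the 2-cell-like state, a rare and transient condition of embryonic stem cells, moved upward as a list from very low levels. Of 11 measured members, 1 rose, Zscan4e, none fell and 10 did not pass, with the same count of 1 when adjusted over the list alone. The list median was a log2 fold change of 1.21 (camera adjusted p = 0.00805), above all of 10000 matched random lists. Zscan4e had a mean of 39.6 normalized counts and rose 2.83-fold in the authors' deposited table (log2 1.50, 95% interval 0.60 to 2.396). Zscan4b had a log2 fold change of 1.45 (adjusted p = 0.131) and Usp17lb 2.05 (adjusted p = 0.207) in the authors' deposited table. The members of these families are near-identical copies that share reads, so they are not separate measurements, and with a filter at a mean of 50 too few were left to test the list.

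Repressive chromatin genes, which the series title concerns, passed the list test in the upward direction with a small median. Of 33 measured members, 3 rose, none fell and 30 did not pass, and 8 rose and 1 fell when adjusted over the list alone. The median log2 fold change was 0.05 (camera adjusted p = 0.00418), at percentile 94.1 of 10000 matched random lists, and the call was lost with a preset correlation of 0.05 between genes (adjusted p = 0.0735). Those that rose were Wiz, a partner of the histone H3 lysine methyltransferases Ehmt1 and Ehmt2 (log2 0.32), the histone demethylase Kdm3a (0.32) and the imprint-protecting zinc finger factor Zfp57 (0.18), by the authors' deposited table. Kdm3a removes methyl groups from histone H3 lysine 9, which Ehmt1 and Ehmt2 add, so the members that rose do not all act in the direction of the list's name. Wiz was no longer past the threshold once a trend on transcript length and GC content was subtracted (adjusted p = 0.204).

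**Figure D3:**
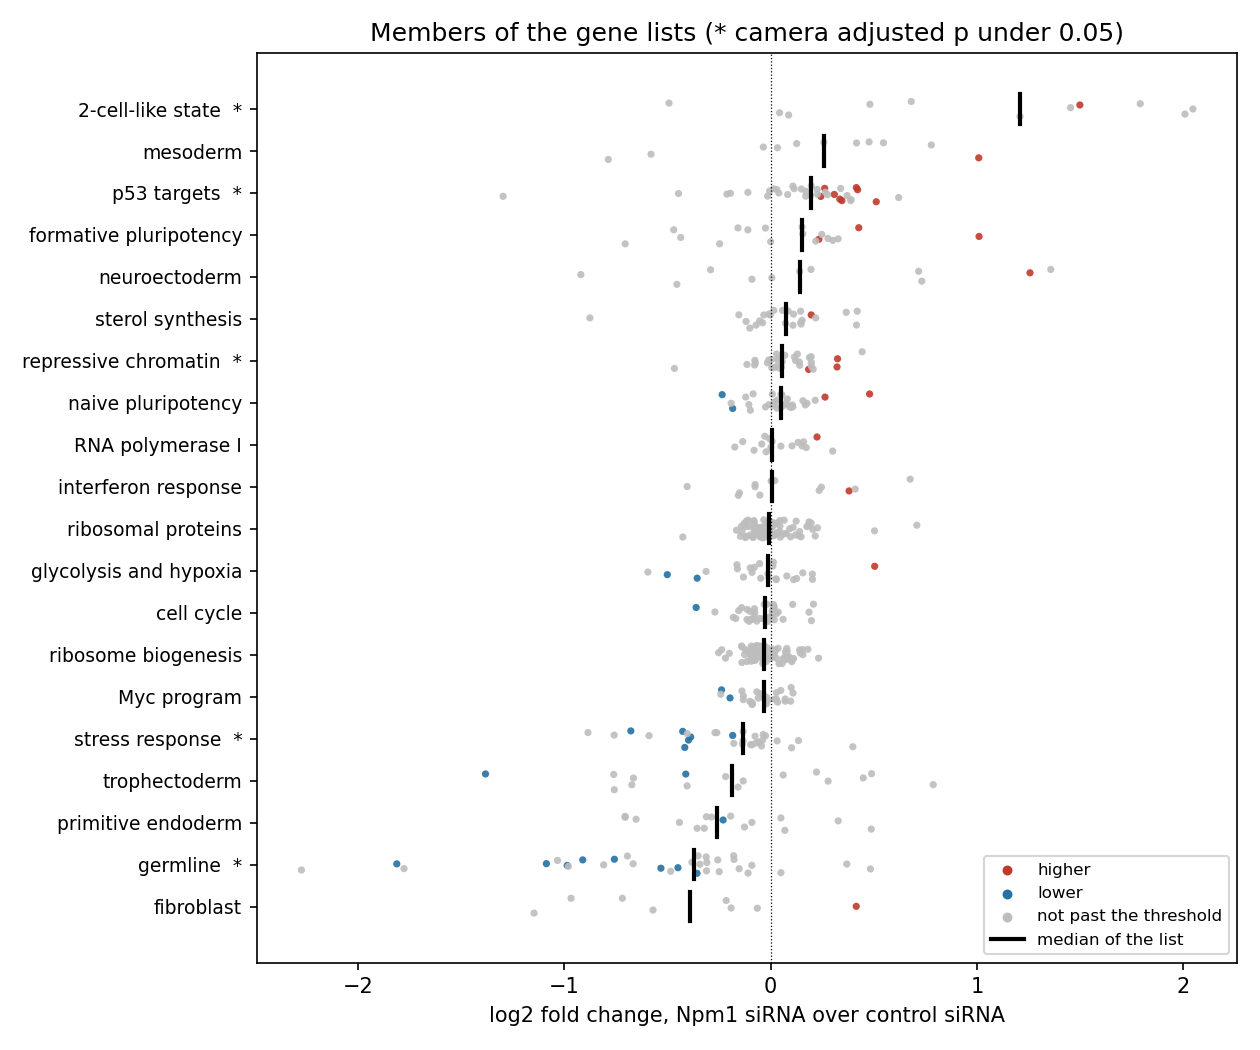
Log2 fold change of Npm1 siRNA over control siRNA (horizontal axis) for each measured member of the 20 lists defined by symbols (vertical axis), with members past the threshold in red (higher) or blue (lower), the others in grey and a black bar for the list median. The medians of the lists marked with an asterisk run from -0.37 for germline genes to 1.21 for the 2-cell-like state, while those of ribosome biogenesis (-0.03) and ribosomal proteins (-0.01) lie close to 0 (values from the authors' deposited table).

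The nucleolar and ribosomal lists gave few or no calls. None of 79 measured ribosome biogenesis factors passed, whether over all genes or adjusted over the list alone, with a median log2 fold change of -0.03 (camera adjusted p = 0.365). That median lay at percentile 0.35 of 10000 matched random lists, and 49 of the 79 values were negative. At an unadjusted p under 0.05 in the authors' deposited table there were 6 of the 79, a smaller share than the 16.3% over all tested genes (2323 of 14284). Ncl, encoding nucleolin, was the nearest at a log2 fold change of -0.22 (95% interval -0.37 to -0.07, adjusted p = 0.0739), and Mybbp1a was at 0.03, in the authors' deposited table. Ncl did pass, as lower, once the trend on transcript length and GC content was subtracted (log2 -0.24, adjusted p = 0.0434). None of 79 ribosomal protein genes passed either, also when adjusted over the list alone. Of these, 10 had an unadjusted p under 0.05 in the authors' deposited table, again a smaller share than over all tested genes. Their median was -0.01 and their mean 0.01, so the signs differ, and the camera adjusted p was 0.570, with the median at percentile 9.03 of its matched lists. Rpl4 was at -0.12 and Rpsa at 0.04 on the log2 scale in the authors' deposited table. Of 17 genes of RNA polymerase I and its factors, 1 rose, the initiation factor subunit Taf1d (log2 0.22 in the authors' deposited table), and 2 rose when adjusted over the list alone (median 0.01, camera adjusted p = 0.216). Taf1d lost its call when fold changes were recentred on the median (adjusted p = 0.0502).

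Pluripotency genes moved in both directions. Of 30 naive markers, Utf1 (log2 0.48) and Sall4 (0.26) rose and Spp1 (-0.24) and Klf5 (-0.18) fell in the authors' deposited table, and 2 rose and 3 fell when adjusted over the list alone (median 0.05, camera adjusted p = 0.365). Pou5f1, Sox2 and Nanog had log2 fold changes of 0.10, 0.01 and -0.03 in the authors' deposited table. Of 18 formative markers, 3 rose, and 4 rose and 2 fell when adjusted over the list alone (median 0.15, camera adjusted p = 0.180). The 3 that rose over all genes were the transmembrane semaphorin Sema6a (log2 1.01), the de novo DNA methyltransferase Dnmt3b (0.43, 95% interval 0.29 to 0.56) and Zfp281 (0.23), by the authors' deposited table.

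Lineage markers gave 1 or 2 calls per list. Of 11 mesoderm markers, Bmp4, a signalling ligand, rose 2.01-fold in the authors' deposited table, and 1 rose and 1 fell when adjusted over the list alone (median 0.26, camera adjusted p = 0.238). Of 11 neuroectoderm markers Sox1 rose, and 4 rose and 2 fell when adjusted over the list alone (median 0.14, camera adjusted p = 0.173). Of 16 trophectoderm markers, Gata2 and the homeobox gene Rhox5 (log2 -0.41 in the authors' deposited table) fell, and 2 rose and 4 fell when adjusted over the list alone (median -0.19, camera adjusted p = 0.203). Of 16 primitive endoderm markers, Sparc, a matrix glycoprotein, fell to 85.2% of control in the authors' deposited table, with the same count of 1 when adjusted over the list alone (median -0.26, camera adjusted p = 0.154). This list passed once the trend on transcript length and GC content was subtracted (camera adjusted p = 0.0468).

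Among growth and metabolism lists, Ccne1, the cyclin of S-phase entry, fell to 77.8% of control in the authors' deposited table, as 1 of 38 cell-cycle genes both over all genes and adjusted over the list alone (median -0.03, camera adjusted p = 0.154). Of 28 genes of the Myc program, the lactate dehydrogenase Ldha (log2 -0.24) and the chaperonin subunit Cct3 (-0.20) fell in the authors' deposited table, and 3 fell when adjusted over the list alone (median -0.03, camera adjusted p = 0.134). Of 25 glycolysis and hypoxia genes, Ndrg1 rose (log2 0.50) and the growth factor Vegfa (-0.50) and the prolyl hydroxylase P4ha1 (-0.36) fell in the authors' deposited table, with the same counts when adjusted over the list alone (median -0.01, camera adjusted p = 0.365). Of 25 sterol genes, 1 rose, and also 1 when adjusted over the list alone (median 0.07, camera adjusted p = 0.171). Of 14 interferon-response genes, the RNA sensor Ddx58 rose (log2 0.38 in the authors' deposited table), 1 also when adjusted over the list alone (median 0.00424, camera adjusted p = 0.570).

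Fibroblast markers were followed because a feeder layer would bring them. Of 8 measured, Vim, an intermediate filament gene that embryonic stem cells also express, rose (log2 0.41 in the authors' deposited table), 1 also when adjusted over the list alone. The list median was -0.39 while the test pointed upward, so their signs differ, and the camera adjusted p was 0.950. Of 10 mitochondrially encoded genes mt-Nd2 fell (log2 -0.23 in the authors' deposited table), and 1 rose and 2 fell when adjusted over the list alone (median -0.05, camera adjusted p = 0.632). None of 15 olfactory and vomeronasal receptor genes passed, over all genes or adjusted over the list alone (median 0.44, camera adjusted p = 0.220), with Olfr718-ps1 at a log2 fold change of 0.31 and Olfr986 at 0.44 in the authors' deposited table. None of 20 clustered protocadherins passed either way, also adjusted over the list alone (median 0.09, camera adjusted p = 0.932), with Pcdhgc3 at 0.22 and Pcdhga12 at 0.29 in the authors' deposited table. Each of these last groups, receptors and protocadherins, had 1 gene at an unadjusted p under 0.05 in the authors' deposited table, a smaller share than the 16.3% over all tested genes. Only 4 replication histone genes were measured in poly(A)-selected RNA, too few to test, and 0 passed adjusted over the list alone, with Hist1h2bc at a log2 fold change of 0.58 and Hist1h4i at 0.61 in the authors' deposited table.

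Among lists not past camera, the medians that lay furthest out among 10000 matched random lists were those of primitive endoderm (percentile 0.78), mesoderm (97.8), formative pluripotency (99.2) and the receptor families (99.5), besides that of ribosome biogenesis. Once the trend on transcript length and GC content was subtracted, the formative median was 0.03, against 0.15 before. Those of primitive endoderm (-0.24), mesoderm (0.20) and the receptor families (0.45) changed less.

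The ribosomal RNA gene arrays of the mouse lie near the centromeres of chromosomes 12, 15, 16, 18 and 19, and the share of called genes on these chromosomes was compared with that of the other autosomes. Of the autosomal genes that rose, 52 of 311 (16.7%) lay there, and of those that fell 46 of 279 (16.5%). Among genes not called the share was 16.5% (2114 of 12812). Fisher's exact test, two-sided, gave p = 0.938 for the genes that rose (odds ratio 1.02) and p = 1 for those that fell (odds ratio 0.999), with an adjusted p of 1 over the 2 directions.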

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

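Recentring, the length and GC trend, the mean threshold giving the most calls, ranks and the preset correlations were chosen after the data were seen. The 318 higher and 296 lower calls became 21 and 37 with a fold of at least 2, and 9 and 12 in a test against a fold of 1.2, which needs a change beyond that fold by more than its error (Tbx20, at log2 1.44 with a standard error of 0.37, was lost). Subtracting the trend on transcript length and GC content, over the 13906 genes with annotation (314 of the higher and 292 of the lower calls), left 208 higher genes, 195 of them among the original calls, and 272 lower genes, 231 of them among the original calls. The cause was not tested beyond the length and GC comparison given with the other observations. With no filter on low means there were 245 higher and 221 lower genes, and with a mean of at least 50 there were 351 and 301. The higher share of all calls was 51.8% as reported, 43.3% after the trend and 48.2% after recentring on the median, which shifted values by 0.00836. Npm1 stayed between -1.15 and -1.09 on the log2 scale under every setting run, and between 4 and 6 lists passed. With a preset correlation of 0.05, the camera adjusted p was 7.98e-05 for germline genes and 0.000139 for p53 targets. It was 0.000522 for the stress response and 0.0423 for the 2-cell-like state. The share of higher genes on rDNA-bearing chromosomes ranged from 15.96% to 23.8%, past no test in any setting run. Among named genes and lists, 12 lost their call without a filter, 10 after the trend, 46 in the test against a fold of 1.2 and 1 (Taf1d) after recentring on the median, while Ncl (log2 -0.24) passed after the trend. No call was reversed in direction, though lists not past the test with medians close to 0, such as ribosomal proteins, changed sign after the trend. Npm1 at a mean of 135425 is far above the means of 10 to 50 at which the median standard error was 0.65.

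No paired analysis was possible because the deposited table has no column per library. For the same reason another normalization, another count model, limma without a trend, other pseudocounts, leaving out each sample, an estimated correlation, fry and other splits of the samples were not run, so whether a call rests on 1 library is not known. Scaling factors without ribosomal protein and mitochondrial genes could not be recomputed either, and recentring the fold changes without these genes gave 289 higher and 313 lower calls and 5 lists.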

Other observations

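The gene groups in this paragraph and the tests on transfer RNA synthetases, ribosomal and Myc lists, X-linked genes and distances between neighbours were chosen after the results were seen. Of 20 cytosolic transfer RNA synthetases, 9 fell, none rose and the rest did not pass, and 0 of 17 mitochondrial synthetases were called, with log2 values from -0.35 to 0.24. Sars was at 80.9% of control in the authors' deposited table (log2 -0.31, adjusted p = 0.000185), and Aars, Gars, Lars, Nars, Tars and Yars also fell. Of 17 genes of serine and one-carbon metabolism, 6 fell, among them Psph (log2 -0.37) and Mthfd1l (-0.23) in the authors' deposited table, and 1 rose. Of 28 genes of protein folding in the endoplasmic reticulum, 8 fell and 2 rose (median -0.11), with Clgn at log2 -0.59 and Serp1 at 0.46 in the authors' deposited table.

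Of 42 large chromatin regulators measured, a group also chosen after its values were seen, 13 rose, none fell and the rest did not pass (median 0.13). Those that rose included the remodeller subunit Smarca2 (log2 1.06) and the histone methyltransferases Setd1b (0.45) and Kmt2d (0.25) in the authors' deposited table. These genes have long transcripts (median 8488 nucleotides), and after the length and GC trend was subtracted 6 of them were called higher and the median was 0.07. Of 27 basement membrane and receptor genes, 6 rose and 3 fell, or 2 and 4 after that trend was subtracted, with Itgb5 at log2 0.74 and Itga5 at -0.60 in the authors' deposited table. The nuclear RNA Neat1 rose (log2 0.34) and Malat1 fell (-0.24) in the authors' deposited table.

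Genes called higher had longer and GC-richer transcripts than other genes, at a median of 4317 nucleotides and 52.6% GC, against 3276 and 48.7% for lower genes and 3188 and 49.4% for genes not called. They were also more abundant, with a median mean normalized count of 1954 against 982 for lower genes and 421 for genes not called. The comparison was not matched on expression. Across 13906 genes, which are not independent replicates, the signed normal quantile had a Spearman rho of 0.10 with GC content and 0.09 with log2 length (permutation p = 0.0001 each, the smallest that 10000 permutations can give). Recentring kept at least 90.9% of the calls in either direction, but it moved values by 0.00836 at most among the 2 recentrings used, so it decides nothing about scaling between the groups. A length and GC bias of the libraries stays open: 70.3% of the calls kept their sign and threshold once the trend was subtracted, between the bounds of 50% and 80% set in advance, and those kept were 195 higher and 231 lower of 606. Such a bias and a change in long, GC-rich genes cannot be told apart without values per library, and neither can RNA integrity, so calls with a small fold and a long transcript may be partly technical.

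The stress response list fell, and the length and GC trend is argued against as the whole cause, since the median was -0.14 after its subtraction. A general fall of growth genes stays open: the lowest median among the ribosome biogenesis, ribosomal protein and Myc lists was -0.034, small beside the stress list's -0.134. All 3 medians were negative, at percentiles 0.35, 9.03 and 3.77 of matched lists. After the trend was subtracted, those of ribosome biogenesis (-0.02) and Myc (-0.01) were closer to zero, and that of ribosomal proteins turned to 0.03. Lower activity of Atf4, the factor that induces amino acid synthesis genes, is another open hypothesis. The median of 12 cytosolic synthetases known as its targets differed by -0.20 from that of the other synthetases, but these genes were picked after their values were seen, so the difference is not a test of it. Atf4 transcript itself was at log2 -0.04 in the authors' deposited table, and its protein, the medium and effects of the siRNA on other transcripts are not addressed by any value here.

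The germline list fell, and low expression is argued against, as the list's median was at percentile 0 of 10000 matched lists, and so is the length and GC trend, after which the median was -0.36. Partial loss of the X chromosome was weighed because 9 members are X-linked, and X-linked genes lay at a difference of -0.050006 from autosomal genes (95% bootstrap interval -0.07 to -0.02), which fell between the bounds first set. The 23 autosomal members had a median of -0.34, with 6 called lower. Loss of the X chromosome would not lower these directly, so it is argued against for them. The 9 X-linked members had a median of -0.69, far below the shift of their chromosome. The bound that weighed them was added after the difference was seen, and the 2 called lower, Rhox2a and Xlr3a, have uncertain values. The shift of the whole chromosome, -0.07 at its lower bound, is too small to give a median of -0.69. That argues against loss of the X chromosome as the whole cause for the X-linked members, while a contribution of the size of that shift stays open. A biological hypothesis is stronger silencing of these genes, as the DNA methyltransferase Dnmt3b rose (log2 0.43 in the authors' deposited table). No other DNA methyltransferase on the fixed lists passed the threshold, so the hypothesis rests on that gene alone. The histone H3 lysine 9 demethylase Kdm3a also rose (log2 0.32 in the authors' deposited table), which would go the other way for genes silenced by that mark. Methylation was not measured, and an effect of the siRNA on other transcripts stays open.

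If loss of nucleolar contacts acted on whole chromosome domains, neighbouring genes may change together. The signed normal quantiles of 11955 adjacent, non-overlapping gene pairs had a correlation of 0.09 (0.088, permutation p = 0.001, the smallest that 1000 permutations can give, and 0.085 after the length and GC trend). It was 0.07 for pairs over 10 kb apart with different symbol stems, 0.05 at a distance of 5 genes, and 0.01 at 50 genes. The value is small, and the test does not separate nucleolar domains from other regional features such as shared enhancers. Without values per library the samples could not be permuted. Whether the correlation comes from the Npm1 siRNA or from other differences between the samples is therefore unknown. A related hypothesis was that higher genes lie in gene-poor regions. They had a median of 17 protein-coding genes within 500 kb against 15 for uncalled genes matched on mean (difference 2, 95% interval -2 to 5). An equal or higher median was the outcome set in advance as going against the hypothesis, so its prediction was not borne out among the tested genes. The interval still includes lower values, so a small difference in that direction is not excluded. Genes with a mean under 10 were left out, and those with a mean of 10 to 50 had a median standard error of 0.65. A release of weakly expressed genes could therefore be missed. Random draws of matched uncalled genes gave a resampling p of 0.164, two-sided.

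Among 40 tests of single chromosomes, 2 of 488 X-linked genes were called higher (odds ratio 0.173, Fisher's exact test adjusted p = 0.0439) and 20 of 457 genes on chromosome 14 were called lower (odds ratio 2.22, adjusted p = 0.0439).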
